A study of Mus musculus with 2 samples.

How the data were processed

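RNA was measured in Lin- Sca-1+ c-Kit+ (LSK) cells, the fraction of mouse bone marrow that holds haematopoietic stem cells and multipotent progenitors. Per the labels, 1 library came from a pool of 12 wild-type (WT) mice and 1 from a pool of 6 miR-146a-/- mice, all C57BL/6J and 10 to 14 weeks old. Total RNA was extracted with a column kit and depleted of ribosomal RNA before library preparation, per the labels' protocols.

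The authors deposited a table of whole-number read counts per Ensembl gene, with no normalisation, and these counts were the only values used. Per the file headers, alignments included splice junctions placed on the genome and duplicate reads were flagged. Whether flagged duplicates were counted, which program counted reads, whether strand was used and which annotation was counted are not given in the sources used here. The submitters' processing notes name STAR 2.5.3a, Salmon 0.9.0 and the mm10 build, without saying which step each served. Because strand use is unknown, reads of overlapping or antisense genes cannot be separated, and near-identical paralogs can share reads.

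Gene symbols, biotypes, positions, transcript lengths and 3' untranslated regions came from the GENCODE M21 annotation of the same genome assembly. Of 39017 gene identifiers, 37693 had a name there. The 1324 without one held 0.286% of WT counts and 0.168% of miR-146a-/- counts.

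Total counts were 35069136 in the WT library and 22231389 in the miR-146a-/- library. Effective library sizes were computed by TMM in edgeR 4.0.16 (R 4.3.3) over the 13880 genes with at least 20 counts summed over both libraries, called measured below. With 1 library per genotype the quasi-likelihood test of edgeR could not be run, so edgeR served for scaling only. No p-value is given. For each gene the log2 ratio of miR-146a-/- over WT used a prior count of 0.5, scaled to each library. Its 95% interval was the exact Clopper-Pearson interval of the binomial share of counts, converted to a ratio. A gene was called higher or lower when the whole interval lay beyond 1.5-fold. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules and animals were pooled. A gene with 0 counts in a library was set at a floor of 3 counts to give a fold. That fold leaves out the counting error of the other library.

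Gene lists were fixed before the data were examined. There were 30, covering reported miR-146a targets, NF-kB, IL6, receptor and interferon signalling, immediate early and heat shock genes, stem and progenitor cell programmes, cell cycle, antigen presentation, markers of other cell types, sex-linked genes, ribosomal proteins, mitochondrially encoded genes, histones and oxidative phosphorylation. Kinases of ribosomal protein S6 and binding-protein genes that share the ribosomal prefix were left out of the ribosomal list. The median log2 ratio of the measured members of each list was placed among 10000 random lists of the same size. Random lists were drawn from measured protein-coding genes in the same 10 bins of mean normalised count. A list stood apart when its median lay outside the central 95% of the random lists. For 30 lists of genes drawn independently, about 1.5 would do so by chance. Genes of a list can vary together and some lists share members, so more than 1.5 could stand apart without any effect of genotype. This percentile describes these libraries, not the genotypes.

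Sites matching bases 2 to 8 of miR-146a-5p were sought in the longest annotated 3' untranslated region of each gene. The median ratio of genes with a site was compared with that of genes without one, matched on 10 bins of mean count and 10 bins of length. The difference was set against those of the other 7-base sequences of the same composition. Genes within 5 Mb of the microRNA gene were compared with windows of the same width along the chromosome, in steps of 1 Mb and with at least 20 measured genes.

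Genes named in the text followed a rule fixed before the data were examined. It took Traf6, Irak1, Tnf, Il6, Nfkbia, Nfkb1 and the microRNA locus. It also took the 12 highest and 12 lowest protein-coding genes with at least 200 counts, ranked by the interval bound nearest to 0, and the 3 highest and 3 lowest of other biotypes. In each list it took up to 2 members in either direction, and for lists of other cell types the 2 most abundant. Some genes that the rule takes are not reported here. Any other gene is named as chosen after its values were seen.

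Alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile scaling, other count filters, a 2-fold threshold, a prior count of 5, the list mean in place of the median, protein-coding genes alone, removal of abundant families, other site lengths and other window widths. Thinning of WT counts to the depth of the other library and adjustment for transcript length and GC content were added after the data were seen. Statistics other than scaling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

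The steps were tested on counts simulated for this comparison from the measured means and library sizes, in which 14010 genes passed the count minimum. The simulated counts varied by Poisson counting error alone, with no spread between pools or libraries. The rates below therefore test the computation and are not error rates of the calls in the real libraries. Of the intervals, 95.5% held the true ratio. Calls were made for 75.8% of 99 genes changed 2-fold and 96.0% of 99 genes changed 4-fold, and for 1 of 13812 unchanged genes. Of 100 unchanged lists of 25 genes, 6 stood apart. A shift of 0.1 in genes with a site was recovered as 0.10 on the log2 scale.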

Results

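The libraries compared LSK cells of young WT mice with LSK cells of mice that lack miR-146a, a microRNA induced by NF-kB that represses adaptors of Toll-like and IL-1 receptor signalling. Each genotype had 1 library from 1 pool of animals, so no difference below has a replicate check, and each statement compares the libraries. Depth was 35069136 counts in the WT library and 22231389 in the miR-146a-/- library, with 19383 and 18309 genes having a count. Protein-coding genes held 81.4% of WT counts and 51.5% of miR-146a-/- counts.

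Much of that gap lay in features with ribosomal RNA sequence. Gm42418, a non-coding gene in a ribosomal repeat on chromosome 17, held 2.131% of WT counts (95% Clopper-Pearson interval 2.126 to 2.136%) and 27.19% of miR-146a-/- counts (27.17 to 27.21%); it was chosen after its values were seen. Of genes outside the protein-coding class with at least 200 counts, Mir6236, Gm15564 and Gm24270 ranked highest by the interval bound nearest to 0. Mir6236 had 24044 counts in WT and 600296 in miR-146a-/-, a log2 ratio of 6.12 (6.10 to 6.14). The ratios of Gm15564 and Gm24270 were 5.61 and 5.56. Ratios below are relative to TMM scaling, under which the median over all measured genes was -0.01. Scaled by total counts alone, that median was -0.83, and 17 of the 30 list medians below changed sign. The log2 ratio of library sizes, miR-146a-/- over WT, was -1.48 by TMM and -0.66 by total counts. By total counts of protein-coding genes alone it was -1.32, so most of the shift by total counts lay outside protein-coding genes.

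The targeted gene gave no check of the labels. Mir146, at chromosome 11, 43374397 to 43374461 on the minus strand (mm10), had 0 counts in both libraries. A hairpin this short is seldom captured in a library of long RNA, so absence from the miR-146a-/- library could not be told from absence of capture. No other gene in the table overlapped this position.

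Relative to WT, the miR-146a-/- library held more transcript of immediate early genes, NF-kB response genes, MHC class II genes and interferon-stimulated genes, and less of DNA replication, histone and nuclear oxidative phosphorylation genes. Of 13880 measured genes, 742 were higher and 212 were lower by the rule on counting intervals. Higher genes made 77.8% of the calls, against 1.94% by total counts, where 140 genes were higher and 7078 lower. Intervals excluded 0 for 7926 genes, while the SD of the log2 ratio over 10365 protein-coding genes with at least 200 counts was 0.43.

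**Figure D1:**
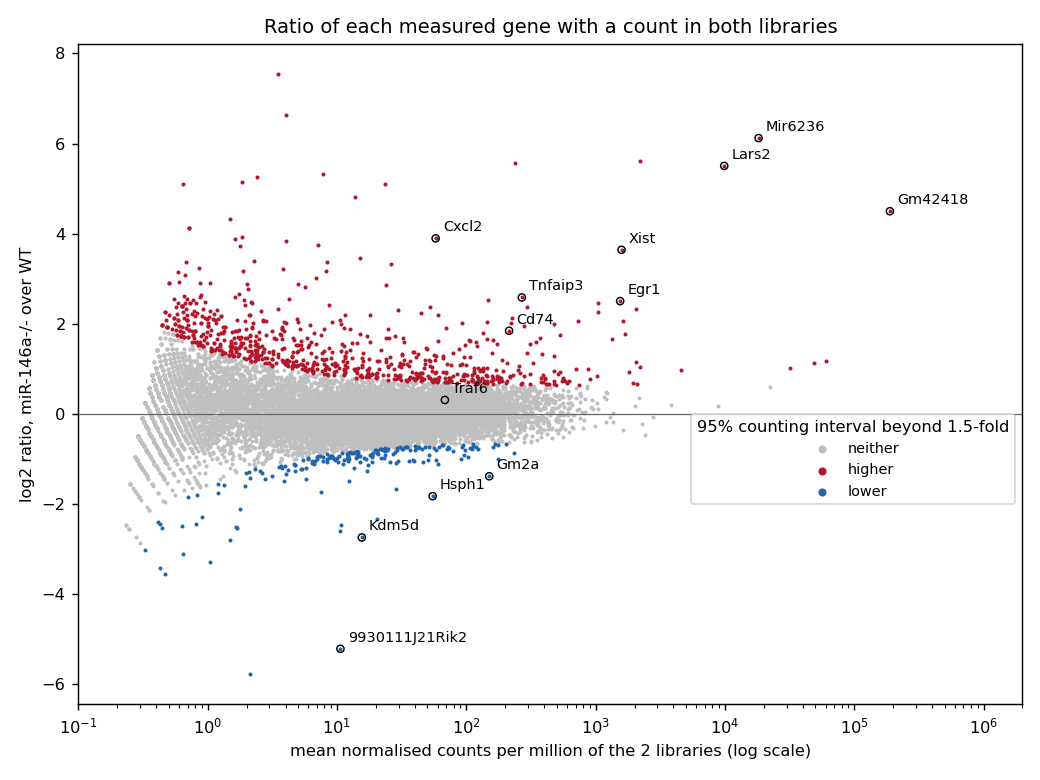
Log2 ratio of miR-146a-/- over WT (vertical axis) against mean normalised CPM of the 2 libraries (horizontal axis, log scale), with 1 point per measured gene that had a count in both libraries. Red points are higher and blue points lower by the 95% counting interval, and Lars2 stands at 5.50 and 9930111J21Rik2 at -5.23.

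Among protein-coding genes, 538 were higher and 178 lower. The highest by the bound of the interval was Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, at 5.50 (5.48 to 5.52), moving with the ribosomal features above. Next were the chemokines Cxcl2 (340 and 1815 counts, log2 ratio 3.89, 3.73 to 4.07) and Cxcl10 (117 and 463 counts, 3.46, 3.17 to 3.77). They were followed by Phlda1 (3.32), the zinc-finger factor Egr2 (3.37), the stress cytokine Gdf15 (3.17), Egr3 (2.86), Tnfaip3 (2.58), Egr1 (2.498), Astl (2.88), Klf4 (2.52) and the MAP kinase phosphatase Dusp1 (2.46). Tnfaip3 encodes A20, an enzyme that restrains NF-kB signalling.

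The lowest protein-coding gene was 9930111J21Rik2, a predicted interferon-inducible GTPase gene on chromosome 11 from 49015874 to 49051242, with 966 counts in WT and 9 in miR-146a-/- (-5.23, -6.40 to -4.34). It has close paralogs beside it and is overlapped by another gene, so its count is uncertain. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y followed. The others were the chaperone Hsph1 (-1.84), the histone genes Hist1h4m (-1.67) and Hist1h4b (-1.28), which have near-identical copies, Ankrd6 (-1.74), the lysosomal activator Gm2a (-1.39), Sdf2l1 (-1.50) and Rhbdl3 (-1.46). Outside the protein-coding class, the antibody segments Igkv10-96 and Ighv1-76 had 575 and 392 counts in WT and 0 in miR-146a-/-. Against the floor of 3 counts they were 68.8-fold and 46.9-fold lower, and the upper bounds of their 95% intervals were -5.80 and -5.25 (log2). The kappa constant gene Igkc was at -1.11.

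All 25 measured immediate early genes, which respond within minutes to stimulation, were higher in the miR-146a-/- library. Their median log2 ratio was 2.02, or 4.05-fold, where random lists gave -0.09 to 0.25 in 95% of draws. Egr2 had 68 counts in WT and 254 in miR-146a-/-, and Egr3 had 270 and 705. The summed level of the list was 5588 normalised CPM in WT and 22441 in miR-146a-/-. Immediate early genes also respond to tissue handling, and the heat shock list, with 11 measured members, had a median of -0.22 that did not stand apart. In that list Dnajb1 (0.96) was higher and Hsph1 and Hspd1 (-0.71) were lower, with Bag3 at 0.28.

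The NF-kB and TNF response list had 29 measured members, of which 21 were higher, 0 lower and 8 neither. Its median was 1.16, against -0.16 to 0.15 for random lists. Nfkbia, the inhibitor that NF-kB induces on its own activation, had a log2 ratio of 2.01 (1.95 to 2.07). Tnf was at 2.24 (2.11 to 2.38), with 718 counts in WT and 1222 in miR-146a-/-. Nfkb1 itself was at -0.04 (-0.10 to 0.02). Il6 had 0 and 2 counts, under the floor, so no ratio is given. Receptors and adaptors upstream of NF-kB did not stand apart: of 26 measured members 1 was higher and 0 lower, with a median of 0.01. The DNA sensor Tlr9 was the highest at 1.52 and Rela was at 0.58, while Traf2 and Tradd were at -0.50 and -0.45.

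**Figure D2:**
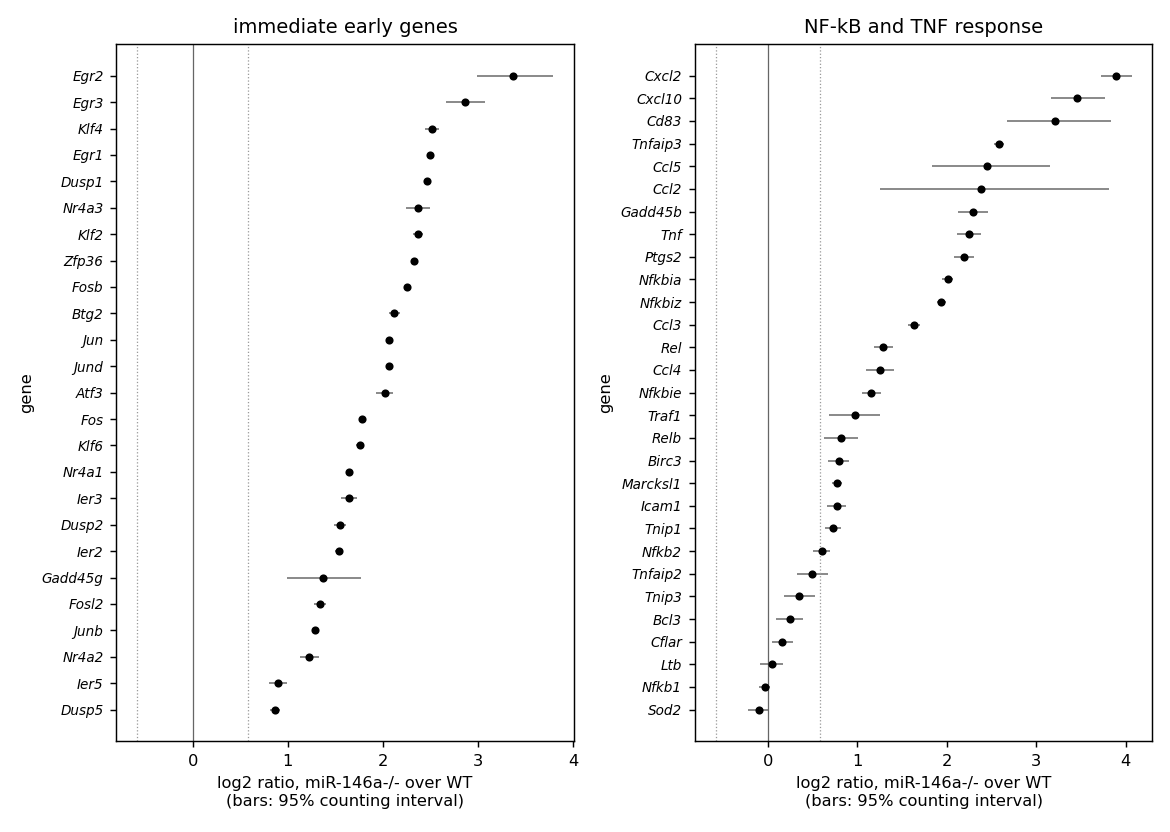
Log2 ratio of miR-146a-/- over WT for each measured immediate early gene (left) and NF-kB response gene (right), with bars for the 95% counting interval and dotted lines at 1.5-fold. The 25 immediate early genes all lie above the upper line, and 21 of 29 NF-kB response genes do so with their whole interval.

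Interferon-stimulated genes were also higher as a list, with a median of 0.55 over 34 measured members, of which 11 were higher and 0 lower. Ifit3 (1.67, 1.33 to 2.03) and the immunity-related GTPase Iigp1 (1.31, 1.19 to 1.44) led it, while Ifi47 was at -0.41 and Ifi35 at -0.38. Of 9 MHC class II presentation genes, 6 were higher and 0 lower, with a median of 1.08. The invariant chain Cd74 was at 1.84 (1.78 to 1.90) and H2-Eb1 at 1.67 (1.53 to 1.82). MHC class I presentation did not stand apart, with 4 of 14 higher, 0 lower and a median of 0.14. B2m (0.93) and H2-Q6 (0.90), which has close paralogs, were higher there, while the immunoproteasome subunits Psmb10 and Psmb8 were at -0.60 and -0.42. The IL6, JAK and STAT3 list had 4 of 22 members higher, 0 lower and a median of 0.18, just outside the random range of -0.18 to 0.17; it no longer stood apart with at least 200 counts or with no filter. Its members Lif (1.22) and Socs3 (0.87) were higher, Socs2 was at -0.93 and Tyk2 at -0.42.

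Reported targets of miR-146a were examined because loss of the microRNA would remove repression from them. Of 24 measured targets 3 were higher, 0 lower and 21 neither, and the list median was 0.26, against -0.15 to 0.20 for random lists; by the list mean it did not stand apart. Relb (0.82), which also belongs to the NF-kB programme, was among the higher members. Elavl1 and Rhoa were at -0.29 and -0.21. The adaptor Traf6, on chromosome 2 from 101678429 to 101701669, had 2850 counts in WT and 1261 in miR-146a-/- (0.30, 0.21 to 0.40). The kinase Irak1 was at 0.02 (-0.05 to 0.08). Of the 24 measured targets, 12 carried a 7-base seed match in the 3' untranslated region.

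Across the transcriptome, genes with a 7-base seed match were not set apart from matched genes. The sequence AGTTCTC occurred in the 3' untranslated region of 1538 measured protein-coding genes, of which 73 were higher and 6 lower. After matching, their median differed by -0.01 on the log2 scale from that of 10706 genes without it. This lay at percentile 36.5 among 419 other sequences of the same composition, whose central 95% ran from -0.04 to 0.05. Matches of 6 bases lay at percentile 1.69, outside the central 95% on the lower side, opposite to what lost repression would give. Only 59 other sequences were available there, so this percentile is coarse. Within 5 Mb of the microRNA gene, 0 of 23 measured genes were higher or lower, against 6.87% of all measured genes and 0 to 20.2% over 116 windows of that width on the chromosome. Within 10 Mb, 7 of 95 were higher and 3 lower (10.5%), where 121 windows ran from 0 to 16.3% with a median of 6.15%.

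Stem and progenitor lists all had positive medians, of different size. Haematopoietic stem cell genes did not stand apart, with 3 of 30 higher, 0 lower and a median of 0.10. The transcription factor Gata2 (0.97) and the endothelial guidance receptor Robo4 (0.78) were higher, and Procr (-0.39) and Ifitm1 (-0.23) were not called. Aged stem cell genes had 6 of 27 higher, 0 lower and a median of 0.30, above random lists except with no filter. Selp, which encodes P-selectin, was at 1.37 and Mt1 at 1.33, while Gda was at -0.72. Granulocyte and monocyte progenitor genes stood higher, with 3 of 22 higher, 0 lower and a median of 0.50. Neutrophil elastase (Elane, 90 and 134 counts) was at 2.04 and Ly6c2 at 1.75, whereas Igfbp4 and Hk3 were at -0.32 and -0.15. Multipotent and lymphoid progenitor genes did not stand apart, with 1 of 20 higher, 0 lower and a median of 0.13. Lsp1 was at 0.51, Ccr9 at -0.91 and the cytokine receptor Flt3 at -0.23.

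Megakaryocyte genes had 4 of 20 higher, 0 lower and a median of 0.37, above random lists. Platelet glycoproteins Gp9 (1.26) and Gp1ba (1.32) were higher. The abundant member Fli1 was at 0.18, and Itgb3 was at -0.23. For erythroid genes, 0 of 13 were higher or lower, and the median of 0.46 stood slightly above the random range of -0.30 to 0.43, but not with at least 200 counts, a prior count of 5 or the mean. Aqp1 was at 0.75 and Cnrip1 at 0.46, and the abundant members Car2 and Tal1 were at 0.12 and -0.08.

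**Figure D3:**
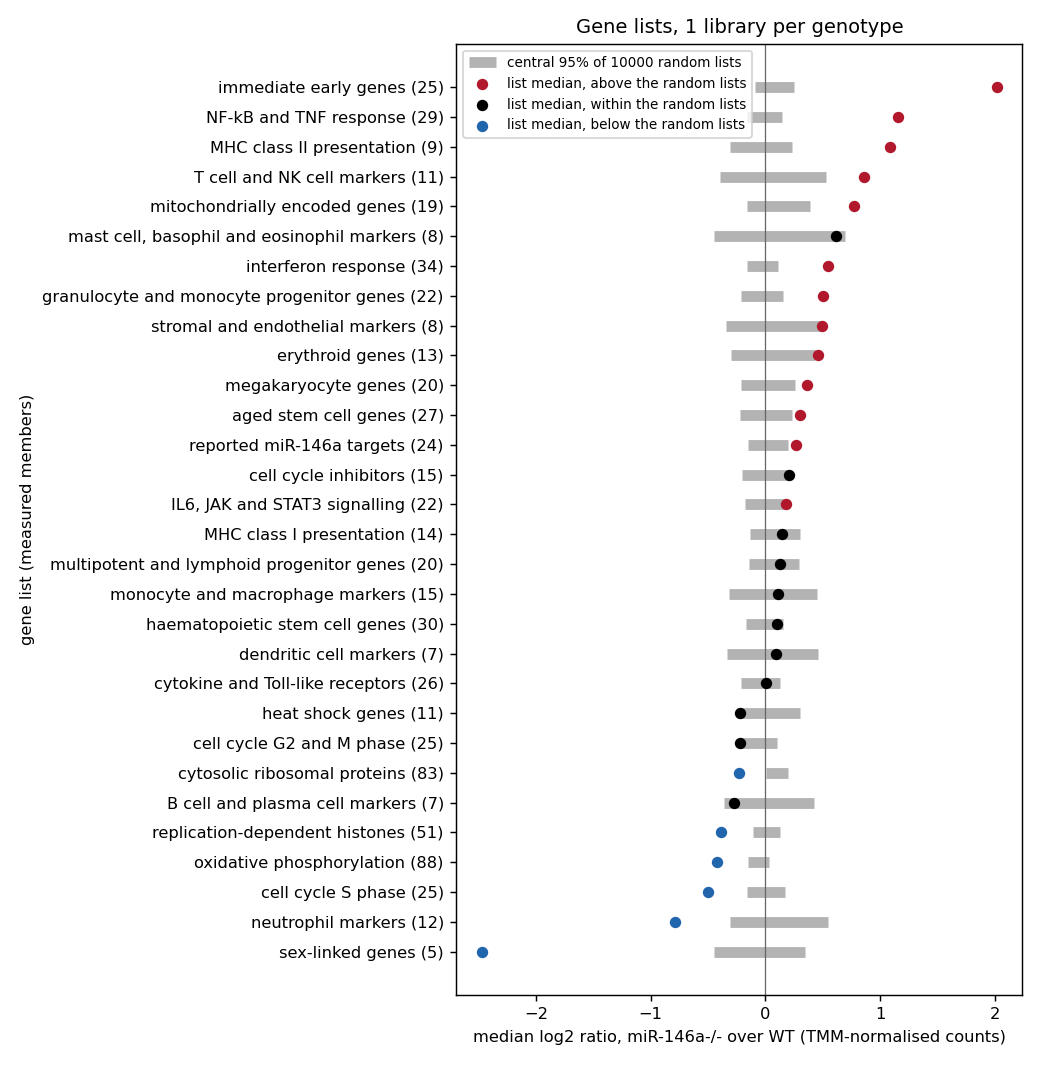
Median log2 ratio of miR-146a-/- over WT for each of the 30 gene lists (points), with the number of measured members in brackets and grey bars for the central 95% of 10000 random lists. Of these, 13 lists lie above and 6 below their random lists, with immediate early genes at 2.02 and sex-linked genes at -2.47.

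Genes of DNA replication were lower as a list. Of 25 S phase genes, 24 had a negative ratio and 2 were called lower, with a median of -0.50 against -0.16 to 0.17 for random lists. The helicase subunit Mcm2 was at -0.67 (-0.73 to -0.61) and the uracil glycosylase Ung at -0.75 (-0.92 to -0.59). For G2 and M phase genes, 0 of 25 were higher or lower, but 22 had a negative ratio and 3 a positive one. The median of -0.223 lay just inside the random range of -0.225 to 0.098 (percentile 2.69) and so did not stand apart. By the list mean (percentile 0.59) and after adjustment for length and GC content (1.0) the list did stand apart, on the lower side. Mki67, a marker of proliferation, was at 0.25 and Cenpe at 0.18, while the checkpoint kinases Bub1 and Bub1b were at -0.64 and -0.56. Of 15 cell cycle inhibitors 5 were higher and 0 lower, with a median of 0.21 that did not stand apart. Cdkn1a, which encodes p21, was at 1.35 (1.26 to 1.44), and Egr1 belongs to this list too. Rbl1 and Ccng1 were at -0.28 and -0.18.

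Replication-dependent histones had a median of -0.38, with 13 of 51 lower and 1, Hist3h2a (1.62), higher; Hist1h2ak was at 0.40. For cytosolic ribosomal proteins the median was -0.23 and 0 of 83 were called, with Rps26 (0.45) and Rpl21 (0.41) at the upper end and Rps2 (-0.63) and Rpl8 (-0.59) at the lower. Nuclear genes of oxidative phosphorylation had a median of -0.42, with 6 of 88 lower and 0 higher. The ATP synthase subunits Atp5e (-1.20) and Atp5j2 (-1.09) were the lowest, and Cox6b2 (0.66) and Atp5l (0.47) the highest. Many of these genes are short, and the median ratio of protein-coding genes went from -0.21 in the decile of shortest transcripts to 0.20 in the decile of longest. After adjustment for transcript length and GC content, the medians were -0.20 for histones, -0.02 for ribosomal proteins and -0.26 for oxidative phosphorylation. Mitochondrially encoded genes were opposite, with 9 of 19 higher, 0 lower and a median of 0.78, led by the ribosomal RNAs mt-Rnr2 (1.18) and mt-Rnr1 (1.13). This list took genes of any biotype, while its random lists were protein-coding. The mitochondrially encoded protein-coding genes held 1.29% of protein-coding counts in WT and 2.28% in miR-146a-/-. By total counts the mitochondrial median was -0.04.

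Markers of other cell types did not move together. Some members were abundant in these libraries, such as Flt3 at 467 and Runx2 at 221 normalised CPM in WT. Ratios of such genes need not reflect other cells. Neutrophil markers were lower as a list, with 3 of 12 lower, 0 higher and a median of -0.79, a call that ended with at least 200 counts (percentile 45.5). The granule proteins Ltf (121 and 6 counts, -2.80) and Ngp (-1.38) were lower, and the most abundant members Padi4 and Anxa1 were at 0.23 and -0.05. Monocyte and macrophage markers had 1 of 15 higher, 0 lower and a median of 0.11, with F13a1 at 1.46, Cd68 at 0.63 and lysozyme (Lyz2) at -0.29. Of 7 dendritic cell markers 0 were called and the median was 0.09; Runx2 was at 0.62. B cell and plasma cell markers had 2 of 7 lower, 0 higher and a median of -0.27, with Jchain at -1.35, Sdc1 at 0.26 and Ighm at -0.27. T cell and NK cell markers stood higher, with 3 of 11 higher, 0 lower and a median of 0.86, a call that ended with at least 200 counts (percentile 87.0). Most of these had few counts: Cd247 (56 and 58 counts) was at 1.52 and Gzmb (9 and 13) at 1.93, while the abundant members Gata3 and Lck were at 0.46 and -0.57. Mast cell, basophil and eosinophil markers had 1 of 8 higher, 0 lower and a median of 0.61 that did not stand apart, with Hdc at 1.33, Cpa3 at 0.67 and Il3ra at 0.47. For stromal and endothelial markers 0 of 8 were called and the median of 0.49 just exceeded the random range of -0.34 to 0.48, a call lost under 4 of the alternatives. Col1a2 was at 1.06, Pecam1 at 0.48 and Pdgfrb at 0.08.

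The sex-linked genes differed between the pools. All had counts in both libraries, as pools of both sexes in different shares would give. The labels do not give the sex of the animals. Xist, the RNA that coats the inactive X chromosome, had 10988 counts in WT and 49105 in miR-146a-/- (3.64, 3.61 to 3.67). The 4 Y-linked genes were lower, from -2.75 for Kdm5d and -2.60 for Eif2s3y to -2.47 for Uty and -2.33 for Ddx3y. These differences go with genotype in every comparison above.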

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

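Adjustment for transcript length and GC content was chosen after the data were seen, as was thinning of WT counts. The 742 higher and 212 lower genes became 140 and 7078 by total counts, 491 and 130 with at least 200 counts, and 294 and 42 beyond 2-fold. Lower genes were 322 with no filter and 136 after the length and GC adjustment. The 2-fold setting is stricter by construction. The filters changed both the genes entered and the scaling, and for them and the adjustment the cause was not tested. DESeq2 and upper-quartile scaling each gave 768 and 200.

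Of 19 lists that stood apart, 12 did so under every alternative run. Total counts shifted the median of all genes from -0.01 to -0.83 and changed the sign of 17 list medians, but only stromal and endothelial markers no longer stood apart (percentile 97.4). With at least 200 counts, 4 lists no longer did: IL6, JAK and STAT3 (97.45), erythroid (88.7), neutrophil (45.5) and T and NK cell (87.0). With no filter these were IL6, JAK and STAT3 (94.2), aged stem cell (97.4) and stromal (89.5) genes, and with a prior count of 5 erythroid genes (96.2). By the mean, miR-146a targets (97.1), erythroid (86.2) and stromal (86.4) genes no longer stood apart, while heat shock (0.38), G2 and M phase (0.59), cell cycle inhibitors (99.95) and B cell markers (1.84) did. After the length and GC adjustment, stem cell genes (99.5), G2 and M phase (1.0), cell cycle inhibitors (98.8) and mast cell markers (97.6) stood apart and stromal markers (96.7) did not. Seed matches of 6 bases lay at percentile 1.69. The adjustment moved the median of ribosomal proteins from -0.23 to -0.02, of histones from -0.38 to -0.20 and of oxidative phosphorylation from -0.42 to -0.26. The cause was not tested for these lists. No paired analysis was possible because each genotype had 1 library, which also rules out leaving a library out. Depth limits the lists of other cell types, whose members often had few counts.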

Other observations

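Further groups were picked after their members' values had been seen, so their ranks among random lists describe the choice as well as the libraries. Chaperone genes went in both directions. All 13 measured HSP90 proteins and partners had a negative ratio, 7 were lower and the median was -0.75, with Fkbp4 at -1.002 and Stip1 at -0.75. The 7 measured CCT chaperonin subunits annotated as protein-coding, which leaves out Cct6a, were negative and 3 were lower (median -0.63). Among 14 chaperones of the endoplasmic reticulum 3 were lower, among them Creld2 (-1.15), and 2 were higher, Hspa5 (0.76) and Dnajb9 (0.78). Of 76 mitochondrial ribosomal proteins 74 were negative and 7 were lower (median -0.49). The medians of these 4 groups after adjustment for length and GC content were -0.62, -0.47, -0.46 and -0.32. By contrast 8 of 11 dual-specificity phosphatases were higher, among them Dusp10 (1.59) and Dusp4 (1.05), as were 7 of 14 Kruppel-like factors, among them Klf9 (1.19) and Klf10 (1.02); both groups share members with the immediate early list.

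Non-coding RNAs leaned the same way. Of 704 antisense, intergenic and other long non-coding RNAs 104 were higher and 1 lower, with a median of 0.41, and of 122 snoRNA genes 15 were higher and 0 lower, with a median of 0.43. Without known strand use, antisense counts cannot be separated from those of their partners. Further classes were also shifted, with medians of 0.80 for snRNA, 0.74 for miRNA and 0.70 for sense intronic genes. Processed pseudogenes, at -0.01 and at -0.06 for transcribed ones, were not. Whether this broad shift is technical was not tested. Among 42 immunoglobulin V, D and J segments, 24 were lower and 5 higher; 16 had 0 counts in the miR-146a-/- library and 4 had 0 in WT. Igkv1-135 and Ighv1-26 had 0 counts in WT and 57 and 48 in miR-146a-/-. Against the floor of 3 counts they were 53.0-fold and 44.6-fold higher, and the lower bounds of their 95% intervals were 5.38 and 5.125 (log2). Of 6 X-linked genes that escape inactivation, Kdm6a (1.07) and Ddx3x (0.70) were higher, with Kdm5c at 0.29 and Eif2s3x at 0.29, and their median of 0.29 did not stand apart.

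Every test below was chosen after the result was seen, except that of the mitochondrial tRNA synthetases, whose prediction came first. Immediate early and NF-kB genes were higher together, with a median of 1.64 over 54 genes. Adjustment for transcript length and GC content argues against such a bias as the whole cause, since the median was then 1.81, where random lists gave -0.07 to 0.14. Mature myeloid cells, which the lineage-negative gate removes, stay open: their markers summed to 1.02 times WT (0.98 to 1.05), but Padi4, Lyz2 and Anxa1 held 77.5% of the WT sum, which could hide a small share, and members went both ways (3 lower, 1 higher). By the bound of 1.2 alone the sum would have argued against such cells; the rule that sets it aside was added after the ratio had been seen. Handling stress could have raised these genes and cannot be told apart from loss of miR-146a, since each genotype was 1 pool: Hspa1a and Hspa1b summed to 1.02 times WT (0.89 to 1.16), yet Dnajb1 was at 1.94 times (1.85 to 2.03). Loss of miR-146a, or the sex makeup of the pools, may also account for the pattern and was not tested apart from them.

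Lars2 was higher along with features of ribosomal RNA sequence. Of 6 measured rRNA genes, with ratios from 0.91 to 5.25 and only 5 to 44 counts in WT, 4 were higher. Other abundant non-coding features, chosen after their values were seen, changed less. Gm26917, beside Gm42418 on chromosome 17, held 2.83% of WT counts and 3.22% of miR-146a-/- counts (log2 ratio 1.01). Gm23935 held 2.38% and 2.01% (0.58). The other 16 mitochondrial tRNA synthetase genes had a median log2 ratio of -0.34 (-0.99 to 0.14), far below Lars2, which argues against a change in that enzyme class. Ribosomal RNA left after depletion, with reads placed in the Lars2 locus, may account for its ratio, but its test was chosen after the ribosomal features had been seen.

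Called genes lay close together about 5.5 to 14.8 Mb from the microRNA gene. All calls within 15 Mb were on the side of higher coordinates. The GTPase genes Gm5431 (1.84) and Gm12185 (1.68) were higher beside 9930111J21Rik2 (-5.23), and Gm2a (-1.39) and Ccdc69 (-0.98) were lower farther out. A passenger segment of another strain around the targeted gene could give this; 12.4% of 169 measured genes within 15 Mb were higher or lower, at percentile 94.2 of 485 windows of that width, which leaves it open, as Irf1, Tnip1 and Igtp there belong to lists that stood apart. Within 5 Mb, where such a segment would be most expected, 0 of 23 were higher or lower. Beside a share of 6.87% over all measured genes, 23 genes are too few for this count to decide. Reads shared between near-identical neighbours could also contribute, but sharing alone would leave the sum of the 4 GTPase genes close to WT. They summed to 1.33 times WT (1.23 to 1.44), and 20.2 normalised CPM lost by 9930111J21Rik2 compare with 34.7 gained by the others. Sharing alone would not give this sum, and a part played by it stays open. Neither could be told apart from an effect of the genotype.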
